A study of Mus musculus with 8 samples.

How the data were processed

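RNA was taken from 3T3-L1 mouse preadipocytes at 4 stages, with 2 libraries per stage: proliferation, quiescence (48 hours at confluence), clonal expansion (10 hours after the cocktail) and differentiation (6 days after it). The labels give the cocktail as dexamethasone at 1 µM, isobutylmethylxanthine at 0.25 mM and insulin at 5 µg/µl. Total RNA was made into unstranded TruSeq libraries and sequenced on an Illumina HiSeq as single reads of 100 nt. The deposited table holds a signal per gene in each library, which the authors made as pseudo-counts with the edgeR package, using relative log expression (RLE) factors to bring read counts to a common library size. Per the submitters' processing notes, CASAVA 1.8.2, edgeR and the mm9 genome were used, with the aligner and gene models not given in the sources used here. Whole reads could not be recovered from these values, so no method for read counts was applied.

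The table had 22798 genes, of which 3848 were below 1 in all libraries and 66 shared a symbol with another. Each read stood for 0.926 to 1.141 pseudo-counts by the spacing of low values. Counting noise was a small part of the spread in the median gene: the squared difference of the 2 libraries of a stage over their sum had medians of 8.24, 16.75, 6.45 and 6.59, where counting noise alone gives 0.455. Over the 13926 to 14463 genes with a mean of at least 10 in a stage, to which these values refer, no value was identical between them. The deviations of same-numbered libraries were correlated above 0.1 for quiescence with clonal expansion (r = 0.354) and with differentiation (0.134), and at 0.013 to 0.072 for the other pairs of stages, so the experiment number was not taken as pairing the libraries and was used as a replicate block only as an alternative.

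Genes with a mean of at least 10 over the 8 libraries were tested, 14647 in all. Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6 read the table, and R 4.3.3 with limma 3.58.1 fitted log2(value + 1) on stage over all 8 libraries, with a mean-variance trend. The fit had 4 residual degrees of freedom and 9.78 with those borrowed across genes. Tests were two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The comparisons were quiescence against proliferation, clonal expansion against quiescence, differentiation against clonal expansion and against quiescence, and quiescence against the mean of proliferation and clonal expansion. The median standard error of a log2 fold change was 0.142, and 0.123 in the last comparison. The smallest called changes were 0.278, 0.228, 0.214, 0.224 and 0.196 on the log2 scale. On simulated data with 67, 67 and 66 genes changed by 1.5, 2 and 4-fold, the fit recovered 20.9% to 28.4%, 59.7% to 76.1% and 78.8% to 87.9% of them in the 4 stage comparisons, and 3.6% to 6.6% of its calls were false. With so few genes changed, the adjustment is stricter there than in the comparisons reported. Each gene was also simulated independently, without the deviations that genes of a real library share. The false share therefore need not hold for the calls reported.

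Gene lists were written from general knowledge before the data were examined, as were the tests, the alternative settings and the rule for named genes. There were 30 lists, counting the unions for imprinted and for matrix genes: imprinted genes by parental copy, collagens, other matrix proteins, matrix remodelling, G1/S and G2/M genes, CDK inhibitors, adipocyte markers, early adipogenic regulators, inhibitors of adipogenesis, responses to glucocorticoids, cAMP and interferon, immediate early genes, cholesterol synthesis, ribosome biogenesis, oxidative phosphorylation, the citric acid cycle with fatty acid oxidation, brown fat, inflammation, actin, the insulin-like growth factor axis, histones, and markers of macrophages and blood, epithelium, endothelium, and muscle, bone and cartilage. Of 77 imprinted genes written down, 76 were in the table and 61 were tested. For histones and brown fat markers, 17 of 37 and 13 of 18 were tested. For macrophage, endothelial, muscle and epithelial markers it was 7 of 17, 7 of 12, 14 of 22 and 6 of 15. Lists share members, such as Cdkn1c. Each was tested in the 5 comparisons with limma's camera at a preset correlation of 0.01, 150 tests adjusted together, and again with an estimated correlation and with fry. Camera called 70 at the preset correlation and 0 with an estimated one (10 with an unadjusted p under 0.05), and fry called 111.

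Named genes were, per stage comparison, the 5 largest rises and 5 largest falls with an adjusted p under 0.05, a mean of at least 200 in the higher stage and both libraries of one stage above both of the other; a fixed set of imprinted, cell cycle, fat cell and matrix genes where the text is about their list; up to 3 members per list and direction with the largest change; and up to 5 rises and 5 falls of imprinted genes. Some genes that this rule names are not reported here. Positions are those of the table, in mm9. Libraries were unstranded, so overlapping pairs such as Kcnq1ot1 and Kcnq1, Airn and Igf2r, Igf2as and Igf2, Copg2 and Mest, Nespas and Gnas, and Blcap and Nnat cannot be told apart where they overlap. Transcript length and GC content came from GENCODE M21 on GRCm38, matched on the NCBI gene number, as the longest transcript, for 13925 of the genes tested.

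Alternatives were other pseudocounts (0.5 and 10), no filter or a mean of at least 50, other scalings (the same total, RLE factors recomputed, quantile normalization), a replicate block, no variance trend, only the stages compared, limma's treat against a 2-fold change, and each library left out in turn. After seeing the data, the fit was also run without experiment 2 of quiescence and clonal expansion, and with a smooth trend on length and GC content (lowess with a span of 0.3) removed. Figures were drawn with matplotlib 3.10.9.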

Results

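Gene expression was measured in 3T3-L1 cells, a mouse line of fibroblast-like cells that can be turned into fat cells by hormones. The 8 RNA-seq libraries came from 4 stages of 2 libraries each: cells dividing exponentially (proliferation), cells held at confluence for 48 hours (quiescence), cells 10 hours after the adipogenic cocktail (clonal expansion), and cells 6 days after it (differentiation). The cocktail held insulin, dexamethasone, a glucocorticoid, and isobutylmethylxanthine, which raises cyclic AMP. The labels number the libraries of a stage as experiments 1 and 2 and do not say whether they came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. The values are pseudo-counts per gene, read counts that the authors adjusted to a common library size, and they summed to 122413485 and 123940067 at proliferation, 127369893 and 125893531 at quiescence, 151529060 and 146570940 at clonal expansion, and 148552972 and 149542130 at differentiation. The gene with the largest share was Col1a2, a chain of type I collagen, at proliferation (1.32% and 1.18%) and quiescence (2.1% and 1.92%). It was Col4a1, a chain of basement membrane collagen, at clonal expansion (1.13% and 1.14%), and Scd1, an enzyme that desaturates fatty acids, at differentiation (4.22% and 4.2%). The 2 libraries of a stage correlated across genes with r of 0.9949, 0.9924, 0.9963 and 0.996 on the log2 scale, in the order of the stages. Their median absolute log2 difference was 0.146, 0.211, 0.123 and 0.127, largest at quiescence. The first principal component held 60.5% of the variance and set the differentiated libraries apart, and the second held 30.6% and set the clonal expansion libraries apart. Values below are means ± SD of pseudo-counts (n = 2 libraries per stage), and log2 fold changes (log2FC) are of value + 1, which understates them for genes with low values. The plot of 12 genes by library shows the range of patterns.

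**Figure D1:**
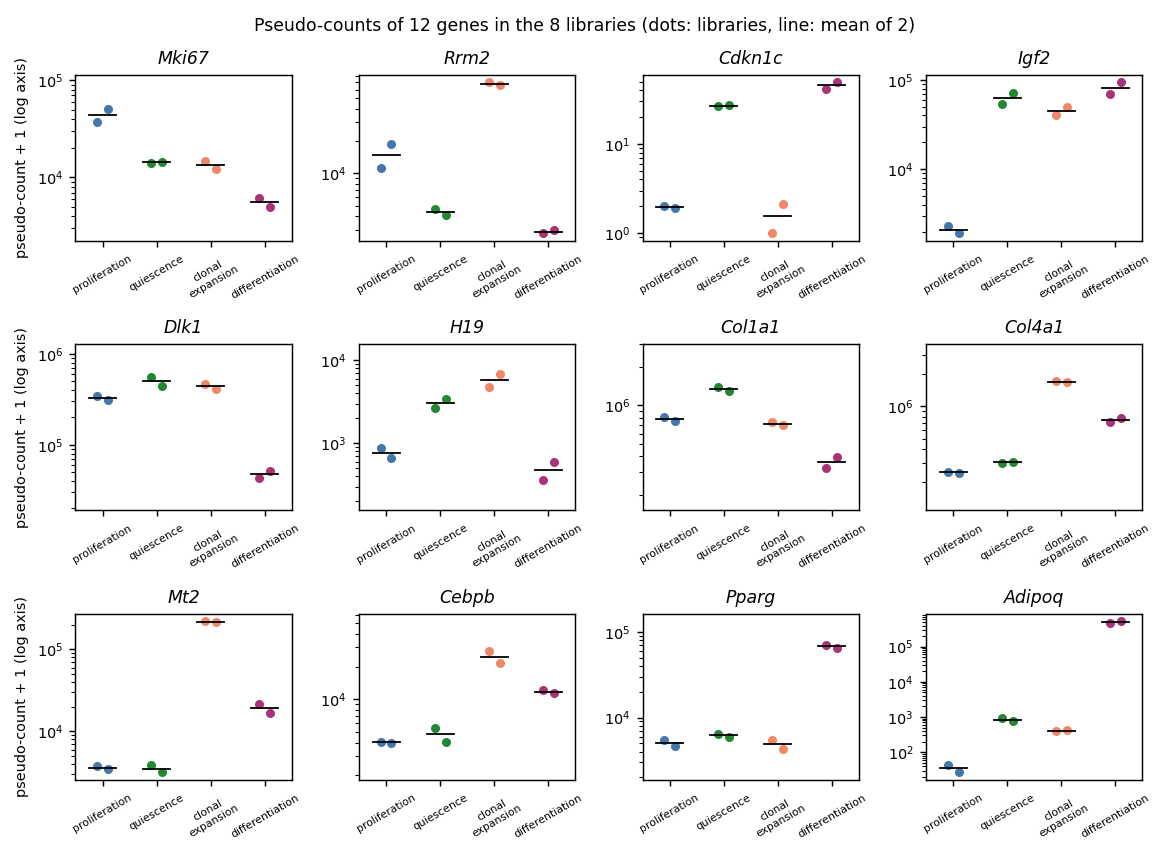
Pseudo-counts of 12 genes in each of the 8 libraries, on a log axis, grouped by stage. Adipoq and Pparg were highest at differentiation, Rrm2, Col4a1, Mt2 and Cebpb at clonal expansion, and Mki67 at proliferation.

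The 2 quiescent libraries differed with transcript length: experiment 2 was lower in the 20% of genes with the shortest transcripts (median log2 difference -0.278) and higher in the 20% with the longest (0.264), as the plot by transcript length shows.

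**Figure D2:**
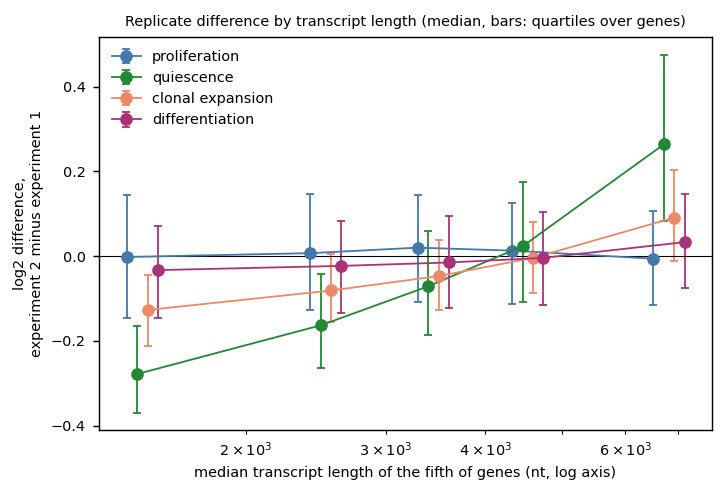
Log2 difference of experiment 2 from experiment 1 of each stage (vertical axis) in 5 equal groups of genes by transcript length (horizontal axis), as medians with quartiles over genes as bars. The rise with length is largest at quiescence (Spearman rho 0.646), less at clonal expansion (0.438) and differentiation (0.130), and near 0 at proliferation (-0.007).

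Cells held at confluence had lower cell cycle transcripts and higher transcripts of secreted matrix proteins and of several imprinted genes, while fat cell genes went both ways. This comparison asked what differs between proliferating and confluent preadipocytes, and division itself was not measured. Of 14647 genes tested, 3472 changed between proliferation and quiescence, 1740 higher and 1732 lower at quiescence, and 579 and 583 of these by at least 2-fold. With the same total per library 1563 were higher and 2116 lower. Without the library proliferation 2, 1304 genes were called. Among the largest rises were those of Agtr2, the type 2 angiotensin receptor, from 5.01 ± 5.94 to 309.6 ± 15.2 (log2FC 6.17, adjusted p = 0.000218) and Clec3b, the secreted plasminogen-binding protein tetranectin, from 411 ± 122.3 to 16960.5 ± 285 (log2FC 5.40). Car3, a carbonic anhydrase abundant in fat and muscle, rose from 7.47 ± 8.83 to 215 ± 29.4 (log2FC 5.23), and Igf2, an insulin-like growth factor, rose from 2107 ± 266 to 62383 ± 11395 (log2FC 4.88, adjusted p = 1.93e-06). The largest falls were in Vip, a neuropeptide, from 206 ± 79.8 to 4.63 ± 0.012 (log2FC -5.15), and Adcyap1r1, a receptor of the same peptide family, from 2761 ± 596 to 292 ± 42.7 (log2FC -3.23). Also among the largest was Krt15, a keratin, from 2128 ± 235 to 340.3 ± 76.0 (log2FC -2.65). Ctgf, a matrix-associated growth regulator, fell from 2067 ± 1768 to 231 ± 3.10 (log2FC -2.83), and Ptgs2, the inducible cyclooxygenase, fell from 6068 ± 5553 to 674 ± 171 (log2FC -2.80). These last 2 falls were -1.82 and -1.69 without proliferation 2, the library with the higher values.

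Genes of DNA synthesis and mitosis fell almost without exception. Of the list of G1/S genes, 0 of 46 rose and 45 fell, 0 and 45 adjusted over the list alone, a fall relative to the other genes tested (adjusted p = 1.9e-24, or adjusted p = 0.474 with an estimated correlation). Of the G2/M list, 0 of 59 rose and 58 fell, 0 and 59 adjusted over the list alone (adjusted p = 9.1e-36, or adjusted p = 0.474 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, fell from 14912 ± 5293 to 4382 ± 441 (log2FC -1.72, adjusted p = 0.000349). Among mitotic genes, Anln, which encodes a scaffold of the cleavage furrow, fell from 25877 ± 8243 to 7208 ± 368 (log2FC -1.81). The proliferation marker Mki67 fell from 44173 ± 9955 to 14332 ± 289.8 (log2FC -1.61) and Ccnb1, cyclin B1, from 5684 ± 1611 to 1779 ± 386 (log2FC -1.66). Cdk1, the kinase it activates, fell from 11068 ± 2903 to 4893 ± 935 (log2FC -1.17). Of the list of CDK inhibitors and growth arrest genes, 8 of 32 rose and 4 fell, 11 and 6 adjusted over the list alone, with no call for the list (adjusted p = 0.147). Pdgfra, a growth factor receptor induced at growth arrest, rose from 48531 ± 8128 to 120081 ± 19056 (log2FC 1.31). Of the inhibitors Cdkn1a and Cdkn1b, the former fell (log2FC -0.42, adjusted p = 0.0365) and the latter was not called (log2FC 0.06, adjusted p = 0.701). A call or sign changed in Cdkn1a (-0.43 to -0.29 without proliferation 1, proliferation 2, quiescence 2, differentiation 1 or differentiation 2) and Cdkn1b (-0.03 without quiescence 2).

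Genes of cholesterol synthesis, ribosome production and the actin cytoskeleton fell as well. All 21 tested members of the cholesterol list fell, also 21 adjusted over the list alone (adjusted p = 9.1e-24, or adjusted p = 0.474 with an estimated correlation), among them the sterol carrier Stard4, from 9770.1 ± 26.2 to 2212 ± 429.6 (log2FC -2.16). Of ribosome biogenesis genes, 0 of 49 rose and 24 fell, 0 and 35 adjusted over the list alone (adjusted p = 4.36e-09, or adjusted p = 0.513 with an estimated correlation). Of actin genes and targets of serum response factor, 0 of 30 rose and 20 fell, 0 and 22 adjusted over the list alone (adjusted p = 6.59e-09, or adjusted p = 0.474 with an estimated correlation). Cnn1, a calponin, fell from 198 ± 59.3 to 53.8 ± 19.96 (log2FC -1.88). Of immediate early genes, 1 of 25 rose and 5 fell, 1 and 9 adjusted over the list alone (adjusted p = 0.000236, or adjusted p = 0.598 with an estimated correlation). Of cAMP response genes, 3 of 30 rose and 6 fell, 4 and 9 adjusted over the list alone, with no call (adjusted p = 0.401).

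Matrix genes rose more often than they fell. Of the extracellular matrix genes, 55 of 114 rose and 15 fell, 59 and 18 adjusted over the list alone (adjusted p = 1.35e-09, or adjusted p = 0.474 with an estimated correlation). Within them, 12 of 23 rose and 3 fell, 13 and 3 adjusted over the list alone among the collagens (adjusted p = 0.000293, or adjusted p = 0.474 with an estimated correlation). In addition, 30 of 54 rose and 7 fell, 31 and 7 adjusted over the list alone among the other matrix proteins (adjusted p = 9.75e-10, or adjusted p = 0.474 with an estimated correlation), and 13 of 37 rose and 5 fell, 15 and 8 adjusted over the list alone among the remodelling genes (adjusted p = 0.017, or adjusted p = 0.483 with an estimated correlation). Mfap4, a microfibril-associated protein, rose from 288 ± 148 to 6229.6 ± 681 (log2FC 4.53, adjusted p = 2.21e-05) and Igfbp4, which binds insulin-like growth factors, from 2605 ± 867 to 58264 ± 3578 (log2FC 4.52). Among collagens, Col15a1 rose from 3409 ± 647 to 19534 ± 1225 (log2FC 2.53), and Col3a1, a fibrillar collagen, rose from 602287 ± 89866 to 1937660 ± 53904 (log2FC 1.69). Mmp2, a gelatinase, rose from 101425 ± 27238 to 337781 ± 13624 (log2FC 1.76), and Lox, which crosslinks collagen, rose from 137946 ± 4895 to 245868 ± 45484 (log2FC 0.82). Col1a1, a chain of type I collagen, rose from 782451 ± 47063 to 1349400 ± 67589 (log2FC 0.79, adjusted p = 0.00602). Falls included Col8a1, a short-chain collagen, from 6733 ± 786 to 2929 ± 103 (log2FC -1.20), and Fn1, fibronectin, from 740596 ± 5732 to 487856 ± 25294 (log2FC -0.60). Some of these calls were lost under another setting, Col1a1 (0.73 without proliferation 2, 0.16 with quantile normalization) and Fn1 (-0.60 without proliferation 1, -0.61 without proliferation 2, -0.55 without quiescence 2).

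Imprinted genes, of which a cell mostly uses the copy from a given parent, are the subject of the series. The list holds genes with imprinting reported in at least some tissues, and expression from each parental copy was not measured. Of the 61 tested, 20 rose and 4 fell, 20 and 6 adjusted over the list alone and 37 were not called, a rise relative to the other genes (adjusted p = 0.0316, or adjusted p = 0.474 with an estimated correlation). Without proliferation 2, 11 rose and 3 fell, without quiescence 2 it was 18 and 8, and with a trend on transcript length and GC content removed, a test chosen after the data were seen, 16 and 6 of the 56 with a known length. Of the genes used from the paternal copy, 11 of 27 rose and 2 fell, 11 and 4 adjusted over the list alone, with no call (adjusted p = 0.0501). Of those used from the maternal copy, 9 of 34 rose and 2 fell, 9 and 2 adjusted over the list alone, with no call (adjusted p = 0.159). Beside Igf2 (gene ID 16002, chromosome 7, 149836673 to 149846940 in mm9), which rose from 2107 ± 266 to 62383 ± 11395 (log2FC 4.88), the largest rise was in Dcn, the small proteoglycan decorin, from 3033 ± 490.1 to 48019.7 ± 3820.2 (log2FC 3.99). The CDK inhibitor Cdkn1c (gene ID 12577, chromosome 7, 150644244 to 150646955) rose from 0.976 ± 0.0854 to 25.8 ± 0.581 (log2FC 3.76, adjusted p = 0.000579), and Igf2as, whose reads cannot be told from those of Igf2 in unstranded libraries where they overlap, from 14.9 ± 3.79 to 197 ± 48.3 (log2FC 3.64). Plagl1, a zinc finger transcription factor (gene ID 22634, chromosome 10, 12810594 to 12851501), rose from 63.6 ± 3.69 to 687 ± 17.4 (log2FC 3.42). The noncoding RNA H19 (gene ID 14955, chromosome 7, 149761437 to 149764051) rose from 771 ± 145 to 3025 ± 546 (log2FC 1.97) and Mest, a hydrolase-like protein, from 893 ± 254 to 3131 ± 299 (log2FC 1.84). Dlk1, the preadipocyte factor that inhibits fat cell formation (gene ID 13386, chromosome 12, 110691033 to 110701546), rose from 327628 ± 24916 to 506354 ± 81596 (log2FC 0.62, adjusted p = 0.018), and Igf2r, the receptor that clears Igf2, rose from 95860.2 ± 17609 to 153613 ± 24822 (log2FC 0.68). The 4 falls were in Dhcr7, Slc38a4, Peg10 and Atp10a. Dhcr7, a cholesterol synthesis enzyme, fell from 8570.0 ± 936 to 3392 ± 366 (log2FC -1.34) and Slc38a4, an amino acid transporter, from 26997 ± 3135 to 12405 ± 1285 (log2FC -1.12). Peg10, a retrotransposon-derived gene, fell from 30488 ± 109 to 17204 ± 3485 (log2FC -0.84), and Atp10a, a phospholipid transporter, from 4675 ± 582 to 2778 ± 276 (log2FC -0.75). Peg3, a zinc finger gene, had 38522 ± 23254 at quiescence against 26562 ± 2665 (log2FC 0.39, adjusted p = 0.419), and Grb10, an adaptor that restrains insulin signalling, had 507 ± 16.9 against 699 ± 262 (log2FC -0.41, adjusted p = 0.312). The calls of some of these genes depended on a library or a scaling, Dlk1 (0.54 without proliferation 2, 0.46 without quiescence 1, 0.33 with quantile normalization), Igf2r (0.49 without proliferation 2), Peg10 (-0.84 without proliferation 1, -0.84 without proliferation 2, -0.63 without quiescence 1) and Peg3 (1.05 without quiescence 1, -0.26 without quiescence 2). The imprinted gene Meg3 had a mean below 10 and was not tested. The heat map of imprinted genes shows each library.

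**Figure D3:**
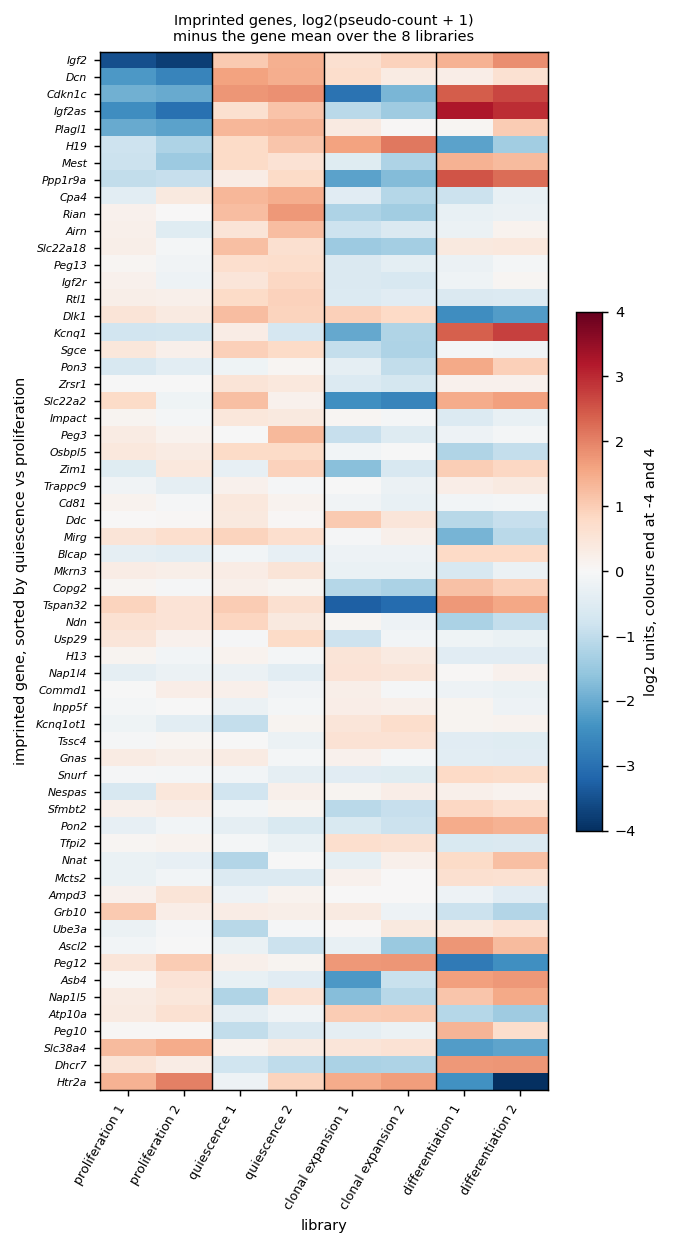
Heat map of the 61 imprinted genes tested (vertical axis, sorted by the change from proliferation to quiescence) in the 8 libraries (horizontal axis), as log2(pseudo-count + 1) minus the gene's mean over the libraries, with colours ending at -4 and 4. Genes at the top, such as Igf2, Dcn and Cdkn1c, were higher at quiescence than at proliferation in both libraries.

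Some genes of mature fat cells rose before any cocktail was given, and others fell. Of adipocyte genes, 18 of 49 rose and 13 fell, 19 and 13 adjusted over the list alone (adjusted p = 0.0198, or adjusted p = 0.598 with an estimated correlation). Adipoq, the hormone adiponectin, rose from 34.0 ± 11.8 to 827 ± 118 (log2FC 4.60, adjusted p = 2.24e-06) and Cfd, the protease adipsin, rose from 14.2 ± 7.60 to 307 ± 154 (log2FC 4.34). Scd1 fell from 33027 ± 1571 to 10905 ± 315 (log2FC -1.60). Cebpa, a transcription factor of late fat cell formation, rose from 1877 ± 386 to 4222 ± 501 (log2FC 1.18). Pparg, the nuclear receptor that drives fat cell formation, was at 6169.9 ± 404 against 5070.1 ± 545 and was not called (log2FC 0.29, adjusted p = 0.143), nor were Cebpb (log2FC 0.23, adjusted p = 0.322) and Cebpd (log2FC -0.11, adjusted p = 0.626), which act earlier. Fabp4, a fatty acid binding protein, fell from 2733 ± 8.67 to 2048 ± 441 (log2FC -0.43, adjusted p = 0.046). Of early adipogenic regulators, 6 of 24 rose and 2 fell, 7 and 2 adjusted over the list alone, with no call (adjusted p = 0.387). Of inhibitors of adipogenesis, 6 of 28 rose and 6 fell, 8 and 7 adjusted over the list alone, with no call (adjusted p = 0.756). Calls that changed with a setting were Fabp4 (-0.44 to -0.21 without proliferation 1, proliferation 2, quiescence 2, clonal expansion 1, clonal expansion 2, differentiation 1 or differentiation 2, -0.42 with quantile normalization), Pparg (0.29 with a replicate block), Cebpb (0.45 without quiescence 2) and Cebpd (0.03 without quiescence 2).

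Several other groups were also tested. Of glucocorticoid response genes, 11 of 26 rose and 3 fell, 11 and 4 adjusted over the list alone (adjusted p = 0.0275, or adjusted p = 0.474 with an estimated correlation). Of interferon response genes, 8 of 35 rose and 1 fell, 8 and 1 adjusted over the list alone (adjusted p = 0.00308, or adjusted p = 0.653 with an estimated correlation). Of inflammatory genes, 5 of 24 rose and 4 fell, 5 and 8 adjusted over the list alone, with no call (adjusted p = 0.944) and with a median fold change below 0 and a mean above it. Libraries scaled to the same total gave 5 rises and 6 falls for that list. C3, a complement component, rose from 8752 ± 1618 to 81932 ± 4729 (log2FC 3.24). Of the insulin-like growth factor axis, 8 of 20 rose and 3 fell, 10 and 4 adjusted over the list alone, with no call (adjusted p = 0.0612). Of replication-dependent histones, whose reads may be shared between copies, 3 of 17 rose and 0 fell, 4 and 1 adjusted over the list alone, with no call (adjusted p = 0.3). There was also no call for oxidative phosphorylation, where 0 of 65 rose and 2 fell, 0 and 0 adjusted over the list alone (adjusted p = 0.0951), for the citric acid cycle and fatty acid oxidation, where 2 of 40 rose and 1 fell, 0 and 1 adjusted over the list alone (adjusted p = 0.522), or for brown fat markers, where 0 of 13 rose and 0 fell, 0 and 0 adjusted over the list alone (adjusted p = 0.394). With the same total per library, the citric acid cycle list had 1 rise and 4 falls.

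**Figure D4:**
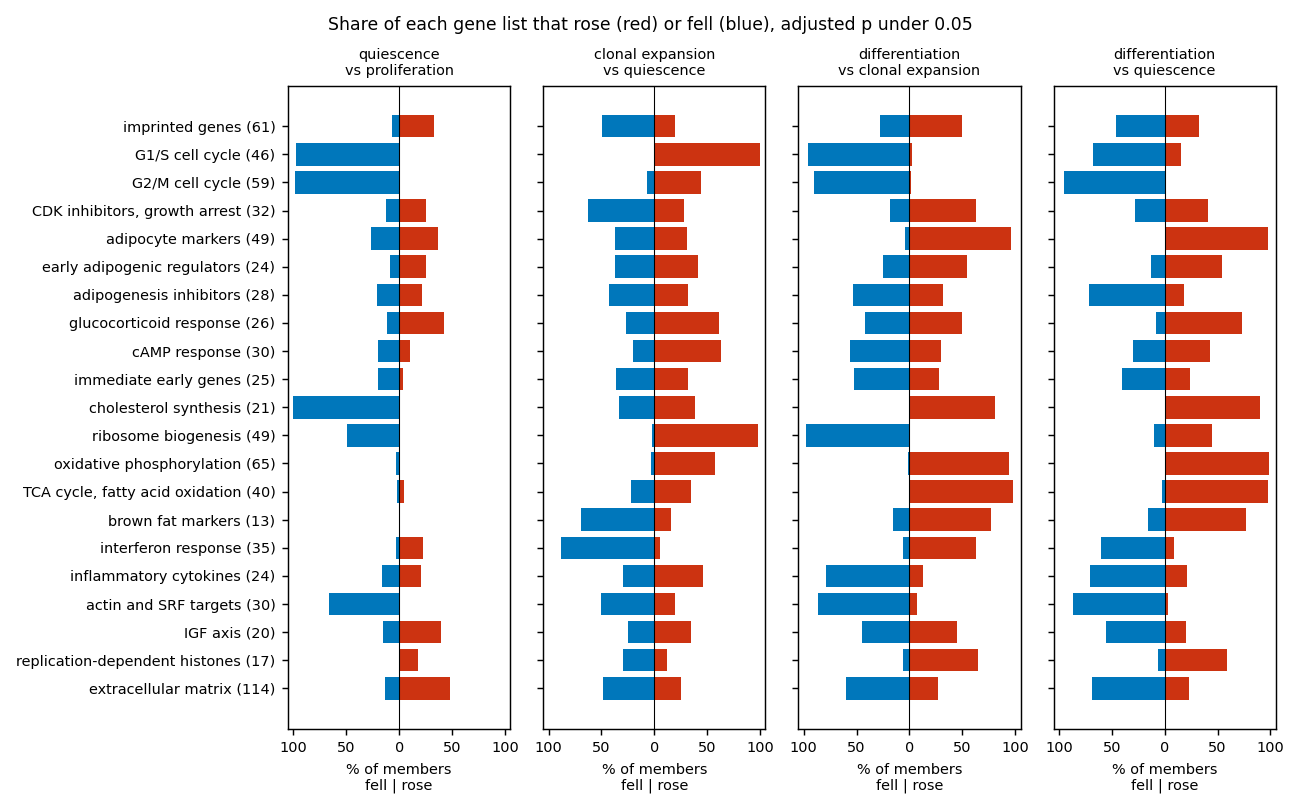
Share of the tested members of each of 21 gene lists that rose (red, to the right) or fell (blue, to the left) in the 4 stage comparisons, in percent, with the number of tested members beside each list. Adipocyte genes rose and both cell cycle lists fell in differentiation against clonal expansion, in every scaling tried, whereas the citric acid cycle, inflammatory, early adipogenic, cholesterol, insulin-like growth factor, histone and CDK inhibitor lists each turned direction under a scaling in at least 1 comparison.

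Within 10 hours of the cocktail, quiescent cells raised genes of DNA synthesis, ribosome production and the hormone response, and lowered interferon genes and many matrix and imprinted genes. This comparison asked how cells at rest respond to the inducers as they enter the round of division called clonal expansion. Of 14647 genes tested, 10071 changed, 5038 higher and 5033 lower at clonal expansion, and 2117 and 2910 of these by at least 2-fold. With libraries scaled to the same total, the median of all genes shifted by -0.239 on the log2 scale and 37.4% of the called genes were higher (3768 higher and 6302 lower), so directions are relative to the scaling. The largest rises were in Pip, a secreted protein known from prolactin response, from 2.32 ± 2.04 to 10329 ± 1645 (log2FC 11.75, adjusted p = 3.12e-07) and Ramp3, a partner of the calcitonin-like receptor, from 20.9 ± 12.9 to 21959 ± 3323 (log2FC 10.10). Next were Retnla, a resistin-like protein, from 0.468 ± 0.662 to 841 ± 191 (log2FC 9.22), and Ear1, a ribonuclease of a family of close copies that may share reads, from 14.3 ± 7.25 to 6559.9 ± 579 (log2FC 8.83). Next was Akp3, an alkaline phosphatase, from 0.941 ± 1.33 to 674 ± 365 (log2FC 8.52). The largest falls were in Ifi47, an interferon-induced GTPase, from 1045 ± 0.0906 to 3.05 ± 2.42 (log2FC -8.16), and Dkk2, a Wnt modulator, from 393 ± 32.4 to 1.63 ± 0.999 (log2FC -7.28). Next were Sycp2, a component of the meiotic synaptonemal complex, from 5467 ± 839 to 57.8 ± 18.5 (log2FC -6.57), and Sema5b, a semaphorin, from 296 ± 27.1 to 2.499 ± 1.69 (log2FC -6.49). Next was Sh2d3c, a signalling adaptor, from 1624 ± 92.6 to 18.0 ± 1.18 (log2FC -6.42).

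Genes that respond to the cocktail's hormones rose more often than they fell. Of glucocorticoid response genes, 16 of 26 rose and 7 fell, 16 and 7 adjusted over the list alone (adjusted p = 0.00656, or adjusted p = 0.474 with an estimated correlation). Lcn2, the secreted lipocalin, rose from 151.6 ± 2.58 to 32687 ± 4683 (log2FC 7.74, adjusted p = 1.21e-08). Mt2, a metallothionein, rose from 3532 ± 496 to 216196 ± 5561 (log2FC 5.94), and Zbtb16, a zinc finger factor, rose from 300.2 ± 97.0 to 6366 ± 1146 (log2FC 4.43). Of cAMP response genes, 19 of 30 rose and 6 fell, 19 and 6 adjusted over the list alone (adjusted p = 0.00663, or adjusted p = 0.504 with an estimated correlation). Fosl1, a Fos family member, rose from 378 ± 20.6 to 11448 ± 30.8 (log2FC 4.92) and Rgs2, a regulator of G protein signalling, from 2294 ± 89.8 to 27439.5 ± 3662 (log2FC 3.57). Immediate early genes went both ways, as 8 of 25 rose and 9 fell, 8 and 9 adjusted over the list alone, with no call (adjusted p = 0.822). Myc, a growth regulator, rose from 2928 ± 189.5 to 31118 ± 581 (log2FC 3.41), while Egr1, an early zinc finger factor, fell from 22203 ± 1092 to 3511 ± 264 (log2FC -2.66). Of early adipogenic regulators, 10 of 24 rose and 9 fell, 10 and 10 adjusted over the list alone, with no call (adjusted p = 0.923) and with a median and a mean below 0 where the test pointed up. The other scalings gave more falls than rises for that list (9 rises and 11 falls with the same total, 9 and 12 with quantile normalization). Cebpb rose from 4764 ± 1009 to 24714 ± 4487 (log2FC 2.38, adjusted p = 1.01e-06) and Cebpd from 4069 ± 556 to 12903 ± 1275 (log2FC 1.67).

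DNA synthesis genes rose at this time, as did some mitotic genes. All 46 genes of the G1/S list rose, also 46 adjusted over the list alone (adjusted p = 2.75e-15, or adjusted p = 0.474 with an estimated correlation). Rrm2 rose from 4382 ± 441 to 68294 ± 3166 (log2FC 3.96, adjusted p = 2.3e-07) and Ccne2, cyclin E2, from 457 ± 5.44 to 4695 ± 55.9 (log2FC 3.36). Of the G2/M list, 26 of 59 rose and 4 fell, 21 and 4 adjusted over the list alone (adjusted p = 0.0233, or adjusted p = 0.839 with an estimated correlation), against 14 rises and 7 falls with the same total per library. Top2a, a topoisomerase, rose from 14708 ± 377 to 59309.7 ± 4408 (log2FC 2.01) and Ccnb2, cyclin B2, fell from 1986 ± 497 to 1000.0 ± 288 (log2FC -0.996). Cdk1 rose from 4893 ± 935 to 9074 ± 687 (log2FC 0.90), and neither Mki67 (log2FC -0.09, adjusted p = 0.625) nor Ccnb1 (log2FC 0.27, adjusted p = 0.305) was called. Of CDK inhibitors and growth arrest genes, 9 of 32 rose and 20 fell, 10 and 20 adjusted over the list alone (adjusted p = 0.0248, or adjusted p = 0.474 with an estimated correlation), and 5 rose and 20 fell with the same total or quantile normalization. Cdkn1b fell from 12895 ± 1130.1 to 5949.6 ± 236 (log2FC -1.11) and Gas2, a cytoskeletal protein of arrested cells, from 13613 ± 1463 to 880.1 ± 226 (log2FC -3.97), while Cdkn1a rose (log2FC 0.40, adjusted p = 0.0166). Of ribosome biogenesis genes, 48 of 49 rose and 1 fell, 48 and 1 adjusted over the list alone (adjusted p = 5.88e-18, or adjusted p = 0.474 with an estimated correlation). Nop56, a nucleolar protein, rose from 7993 ± 607 to 68564 ± 4567 (log2FC 3.10). Of oxidative phosphorylation genes, 37 of 65 rose and 2 fell, 37 and 2 adjusted over the list alone (adjusted p = 0.000158, or adjusted p = 0.746 with an estimated correlation). This became 24 rises and 8 falls with the same total per library and 24 and 3 with quantile normalization. Cycs, cytochrome c, rose from 236 ± 13.97 to 1292 ± 189.6 (log2FC 2.44). Settings that changed a call or a sign were Cdkn1a (0.27 without quiescence 2, 0.25 without clonal expansion 1, 0.10 with quantile normalization, 0.16 with the same total per library) and Mki67 (0.03 without clonal expansion 2).

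Most interferon genes fell. Of 35 tested, 2 rose and 31 fell, 2 and 31 adjusted over the list alone (adjusted p = 1.82e-08, or adjusted p = 0.474 with an estimated correlation). Ifit3, an antiviral protein, fell from 956 ± 175 to 24.9 ± 1.86 (log2FC -5.20, adjusted p = 8.68e-07) and Gbp2, a guanylate-binding protein, from 2211 ± 42.5 to 71.9 ± 1.75 (log2FC -4.92). Of the insulin-like growth factor axis, 7 of 20 rose and 5 fell, 6 and 4 adjusted over the list alone, with no call (adjusted p = 0.862), a median above 0 and a mean below it. Both the same total and quantile normalization gave 3 rises and 7 falls for that list. Igf1, the growth factor, fell from 26732 ± 3159 to 3517 ± 552 (log2FC -2.93) and Irs1, an insulin receptor substrate, fell from 27215 ± 6202 to 3659 ± 295 (log2FC -2.88). Adipocyte genes had no call (adjusted p = 0.869), as 15 of 49 rose and 18 fell, 15 and 18 adjusted over the list alone. Scd1 rose from 10905 ± 315 to 164230 ± 11918 (log2FC 3.91), whereas Adipoq fell from 827 ± 118 to 409 ± 17.6 (log2FC -1.01) and Cebpa from 4222 ± 501 to 2298 ± 396 (log2FC -0.88). Pparg fell from 6169.9 ± 404 to 4844 ± 775 (log2FC -0.36), and Fabp4 was not called (log2FC 0.14, adjusted p = 0.387). A call or sign changed in Pparg (-0.36 to -0.19 without quiescence 1, clonal expansion 2, differentiation 1 or differentiation 2) and Fabp4 (0.36 without quiescence 1, -0.08 without quiescence 2, -0.10 with the same total per library).

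The basement membrane chains Col4a1 and Col4a2 rose while the fibrillar chains Col1a1 and Col3a1 fell. Of matrix genes, 29 of 114 rose and 55 fell, 29 and 57 adjusted over the list alone, with no call (adjusted p = 0.0663). Nor was there a call within them, where 6 of 23 rose and 12 fell, 7 and 13 adjusted over the list alone among collagens (adjusted p = 0.236), 12 of 54 rose and 28 fell, 12 and 28 adjusted over the list alone among other matrix proteins (adjusted p = 0.0915), and 11 of 37 rose and 15 fell, 11 and 15 adjusted over the list alone among remodelling genes (adjusted p = 0.387). The same total and quantile normalization each gave 7 rises and 19 falls for remodelling genes. Col4a1 rose from 303525 ± 5151 to 1693930 ± 30663 (log2FC 2.48, adjusted p = 3.86e-07) and Col4a2, its partner chain, rose from 231188 ± 7546 to 1025500 ± 7085 (log2FC 2.15). Lama5, a laminin chain, rose from 1452 ± 174 to 9858 ± 681 (log2FC 2.77). Col1a1 fell from 1349400 ± 67589 to 720211 ± 22589 (log2FC -0.91), Col3a1 from 1937660 ± 53904 to 954998 ± 103582 (log2FC -1.02) and Timp4, a metalloproteinase inhibitor, from 864 ± 15.2 to 61.3 ± 20.7 (log2FC -3.84). Lox fell (log2FC -0.37, adjusted p = 0.0493), and Fn1 was not called (log2FC 0.03, adjusted p = 0.863). Settings that changed a call or a sign were Lox (-0.37 to -0.18 without proliferation 1, proliferation 2, quiescence 2, clonal expansion 1, clonal expansion 2, differentiation 1 or differentiation 2, -0.37 with a pseudocount of 10) and Fn1 (-0.02 without quiescence 2, -0.31 with quantile normalization, -0.20 with the same total per library).

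More imprinted genes fell than rose. Of the 61 tested, 12 rose and 30 fell, 12 and 30 adjusted over the list alone, a fall relative to the other genes (adjusted p = 0.0383, or adjusted p = 0.474 with an estimated correlation). By parental copy, 5 of 27 rose and 14 fell, 6 and 14 adjusted over the list alone for the paternal (adjusted p = 0.119) and 7 of 34 rose and 16 fell, 7 and 16 adjusted over the list alone for the maternal (adjusted p = 0.0982), with no call for either. The largest falls were in Cdkn1c, from 25.8 ± 0.581 to 0.577 ± 0.816 (log2FC -4.19, adjusted p = 3.42e-05) and Tspan32, a tetraspanin, from 134 ± 25.3 to 7.33 ± 0.834 (log2FC -4.01). Next were Slc22a2, a cation transporter, from 35.3 ± 17.6 to 2.62 ± 0.289 (log2FC -3.24), and Rian, a noncoding RNA beside Meg3, from 400.4 ± 96.3 to 56.1 ± 4.12 (log2FC -2.79). Next was Ppp1r9a, a phosphatase subunit, from 152.4 ± 34.7 to 26.4 ± 5.49 (log2FC -2.48). The largest rises were in Peg12, a gene of the Prader-Willi region, from 1133 ± 38.1 to 3404 ± 59.3 (log2FC 1.59), and Atp10a, from 2778 ± 276 to 6791 ± 79.4 (log2FC 1.29). Next were Kcnq1ot1, a noncoding RNA whose reads cannot be told from those of the overlapping Kcnq1, from 3502 ± 1749 to 6590.2 ± 679 (log2FC 1.004), and H19, from 3025 ± 546 to 5763 ± 1457 (log2FC 0.92). Next was Nap1l4, a histone chaperone, from 13720.5 ± 1226 to 24423 ± 603 (log2FC 0.83). Plagl1 fell from 687 ± 17.4 to 312 ± 49.1 (log2FC -1.14), Mest from 3131 ± 299 to 1110.5 ± 409 (log2FC -1.54) and Igf2r from 153613 ± 24822 to 63914 ± 1878 (log2FC -1.26). Peg3 fell from 38522 ± 23254 to 13747 ± 2672 (log2FC -1.36) and Igf2 from 62383 ± 11395 to 45183 ± 6361 (log2FC -0.46, adjusted p = 0.0438), while Dlk1 (log2FC -0.19, adjusted p = 0.298) and Grb10 (log2FC -0.17, adjusted p = 0.59) were not called. Without quiescence 1 and without quiescence 2, the rise of Kcnq1ot1 was 0.47 and 1.54, and the fall of Peg3 was -0.70 without quiescence 2. A call or sign changed in Igf2 (-0.46 to -0.27 without proliferation 1, proliferation 2, quiescence 2 or clonal expansion 1), H19 (0.73 without quiescence 1, 0.66 without clonal expansion 2), Plagl1 (-0.62 with quantile normalization), Dlk1 (-0.71 with quantile normalization, -0.43 with the same total per library) and Grb10 (0.11 without clonal expansion 2, 0.32 with quantile normalization).

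Between clonal expansion and day 6, the transcripts of fat cells rose and those of division, ribosome production and much of the matrix fell. This comparison asked what separates the early response from the differentiated culture. Of 14647 genes tested, 10694 changed, 5390 higher and 5304 lower at differentiation, and 3413 and 2715 of these by at least 2-fold. With quantile normalization the median of all genes shifted by -0.117 and 44.7% of the called genes were higher. Among the largest rises were those of 4632428N05Rik, from 2.10 ± 1.92 to 18766 ± 1767 (log2FC 12.71, adjusted p = 2.69e-09) and Adrb3, the adrenergic receptor of fat cells, from 0.486 ± 0.656 to 8489 ± 1649.6 (log2FC 12.54). Others were Retn, the hormone resistin, from 18.9 ± 2.62 to 108811 ± 90.3 (log2FC 12.42), and Gpr81, a lactate receptor, from 3.62 ± 1.59 to 14356 ± 402 (log2FC 11.65). The largest falls were in Pip, from 10329 ± 1645 to 3.12 ± 1.40 (log2FC -11.33) and Ramp3, from 21959 ± 3323 to 35.03 ± 6.48 (log2FC -9.26). Others were H2-M9, a class I-like gene that may share reads with its relatives, from 619.8 ± 20.4 to 0.516 ± 0.72 (log2FC -8.76), and Krt16, a keratin, from 1186 ± 50.8 to 2.94 ± 2.61 (log2FC -8.41). H2-M1, of the same class I-like family, was at 449 ± 10.8 at clonal expansion and listed at 0 or within rounding of it in both differentiated libraries, so no fold is given.

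Most fat cell genes rose. Of adipocyte genes, 47 of 49 rose and 2 fell, 47 and 2 adjusted over the list alone (adjusted p = 1.48e-18, or adjusted p = 0.474 with an estimated correlation). The 2 falls were in Elovl6 (-0.77) and Ucp2, a mitochondrial carrier (-0.58). Adipoq rose from 409 ± 17.6 to 509058 ± 33016 (log2FC 10.28, adjusted p = 4.94e-10), Fabp4 from 2233 ± 166 to 1120470 ± 35782 (log2FC 8.97) and Slc2a4, the insulin-responsive glucose transporter, from 14.7 ± 2.23 to 39248 ± 5422 (log2FC 11.29). Pparg rose from 4844 ± 775 to 68445 ± 4025 (log2FC 3.83) and Cebpa from 2298 ± 396 to 78388 ± 2782 (log2FC 5.10). Of early adipogenic regulators, 13 of 24 rose and 6 fell, 13 and 6 adjusted over the list alone, with no call (adjusted p = 0.132). Klf15, a factor of lipid and glucose metabolism, rose from 10.4 ± 1.05 to 18842 ± 1292 (log2FC 10.70) while Cebpb fell from 24714 ± 4487 to 11775 ± 416 (log2FC -1.06). Cebpd fell from 12903 ± 1275 to 4519.5 ± 647 (log2FC -1.52). Of citric acid cycle and fatty acid oxidation genes, 39 of 40 rose and 0 fell, 39 and 0 adjusted over the list alone (adjusted p = 2.95e-14, or adjusted p = 0.474 with an estimated correlation). Acadm, an acyl-CoA dehydrogenase, rose from 6823 ± 541 to 81488 ± 4017 (log2FC 3.58). Of oxidative phosphorylation genes, 61 of 65 rose and 1 fell, 61 and 1 adjusted over the list alone (adjusted p = 5.93e-12, or adjusted p = 0.536 with an estimated correlation). The fall was in Atp5g1, an ATP synthase subunit (-0.61). Of cholesterol genes, 17 of 21 rose and 0 fell, 18 and 0 adjusted over the list alone (adjusted p = 1.66e-06, or adjusted p = 0.474 with an estimated correlation). Of brown fat markers, 10 of 13 rose and 2 fell, 10 and 2 adjusted over the list alone (adjusted p = 0.00514, or adjusted p = 0.474 with an estimated correlation). Cidea, a lipid droplet protein, rose from 1.56 ± 0.461 to 596 ± 156 (log2FC 7.85). A call was lost in Elovl6 (-0.62 without differentiation 1).

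Division and ribosome production genes fell back. Of the G1/S list, 1 of 46 rose and 44 fell, 1 and 44 adjusted over the list alone (adjusted p = 1.23e-14, or adjusted p = 0.478 with an estimated correlation). Rrm2 fell from 68294 ± 3166 to 2873 ± 142 (log2FC -4.57, adjusted p = 2.59e-08) and Ccnd1, cyclin D1, from 156782 ± 6190.4 to 8832 ± 2431 (log2FC -4.18). Brca1, a DNA repair gene, rose from 7316 ± 628 to 12538 ± 285 (log2FC 0.78). Of the G2/M list, 1 of 59 rose and 53 fell, 1 and 53 adjusted over the list alone (adjusted p = 1.1e-10, or adjusted p = 0.561 with an estimated correlation). Top2a fell from 59309.7 ± 4408 to 7237 ± 844 (log2FC -3.04) and Mki67 from 13476 ± 1631 to 5580.4 ± 823 (log2FC -1.27). Cdk1 fell from 9074 ± 687 to 3424 ± 392 (log2FC -1.41) and Ccnb1 from 2140.2 ± 446 to 1186 ± 96.7 (log2FC -0.84). Fzr1, an activator of the anaphase complex, rose from 4982 ± 332 to 7037 ± 97.48 (log2FC 0.50). Of CDK inhibitors and growth arrest genes, 20 of 32 rose and 6 fell, 20 and 7 adjusted over the list alone (adjusted p = 0.0218, or adjusted p = 0.474 with an estimated correlation). Cdkn2c, an inhibitor of CDK4 and CDK6, rose from 1176 ± 64.2 to 22079 ± 3547 (log2FC 4.22), and Cdkn1a (log2FC 0.17, adjusted p = 0.23) and Cdkn1b (log2FC 0.20, adjusted p = 0.0872) were not called. Of ribosome biogenesis genes, 0 of 49 rose and 48 fell, 0 and 48 adjusted over the list alone (adjusted p = 1.04e-13, or adjusted p = 0.474 with an estimated correlation). Of histones, which may share reads, 11 of 17 rose and 1 fell, 12 and 1 adjusted over the list alone (adjusted p = 0.0452, or adjusted p = 0.561 with an estimated correlation). With quantile normalization 5 histones rose and 1 fell. Settings that changed a call were Ccnb1 (-0.62 without clonal expansion 1, -0.75 without differentiation 2) and Cdkn1b (0.20 without quiescence 1, 0.20 without quiescence 2, 0.25 with quantile normalization).

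Most matrix, actin and inflammatory genes fell. Of matrix genes, 31 of 114 rose and 68 fell, 31 and 68 adjusted over the list alone (adjusted p = 0.00131, or adjusted p = 0.561 with an estimated correlation). Collagens had no call (adjusted p = 0.512), as 8 of 23 rose and 11 fell, 8 and 11 adjusted over the list alone. Of other matrix proteins, 14 of 54 rose and 32 fell, 14 and 32 adjusted over the list alone (adjusted p = 0.0114, or adjusted p = 0.598 with an estimated correlation). Of remodelling genes, 9 of 37 rose and 25 fell, 9 and 25 adjusted over the list alone (adjusted p = 0.00165, or adjusted p = 0.474 with an estimated correlation). Timp3, a matrix-bound metalloproteinase inhibitor, fell from 9239 ± 1073 to 259 ± 7.94 (log2FC -5.15, adjusted p = 1.12e-09), Timp1 from 37016 ± 2767 to 1371 ± 42.5 (log2FC -4.75) and Col12a1, a fibril-associated collagen, from 101429 ± 18948 to 7976 ± 1397 (log2FC -3.67). Lox fell from 189222 ± 1566 to 51551 ± 6865 (log2FC -1.88) and Fn1 from 498309 ± 5939 to 217817 ± 35589.9 (log2FC -1.20). Col1a1 fell from 720211 ± 22589 to 358594 ± 47009.5 (log2FC -1.01), and Col3a1 was not called (log2FC -0.09, adjusted p = 0.675). Timp4 rose from 61.3 ± 20.7 to 5009 ± 199.97 (log2FC 6.37) and Col15a1 from 7734 ± 55.7 to 63876 ± 700.4 (log2FC 3.05). Of actin genes, 2 of 30 rose and 26 fell, 2 and 26 adjusted over the list alone (adjusted p = 1.34e-06, or adjusted p = 0.474 with an estimated correlation). Acta2, smooth muscle actin, fell from 66991 ± 4749 to 2027 ± 549 (log2FC -5.07). Of inflammatory genes, 3 of 24 rose and 19 fell, 3 and 19 adjusted over the list alone (adjusted p = 0.000273, or adjusted p = 0.474 with an estimated correlation). Il1rl1, the receptor of interleukin 33, fell from 15517 ± 744 to 84.6 ± 27.3 (log2FC -7.54) while C3 rose from 52959.8 ± 2876 to 1395450 ± 163339 (log2FC 4.72). Of interferon genes, 22 of 35 rose and 2 fell, 22 and 2 adjusted over the list alone (adjusted p = 0.00663, or adjusted p = 0.691 with an estimated correlation). Quantile normalization gave 13 rises and 6 falls for them. Gbp2 rose from 71.9 ± 1.75 to 1907 ± 396 (log2FC 4.69). A setting changed the sign or call of Col3a1 (0.02 without clonal expansion 1, 0.04 without differentiation 1, -0.37 with quantile normalization).

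Imprinted genes moved both ways. Of the 61 tested, 30 rose and 17 fell, 30 and 17 adjusted over the list alone, with no call for the list (adjusted p = 0.326), nor for the paternal genes, where 13 of 27 rose and 6 fell, 13 and 6 adjusted over the list alone (adjusted p = 0.522), or the maternal genes, where 17 of 34 rose and 11 fell, 17 and 11 adjusted over the list alone (adjusted p = 0.385). The largest rises were in Cdkn1c, from 0.577 ± 0.816 to 44.5 ± 5.33 (log2FC 4.95, adjusted p = 7.23e-06) and Tspan32, from 7.33 ± 0.834 to 233 ± 20.7 (log2FC 4.81). Next were Igf2as, from 43.3 ± 6.85 to 903 ± 121.6 (log2FC 4.35) and Ppp1r9a, from 26.4 ± 5.49 to 544 ± 79.8 (log2FC 4.32). Next was Kcnq1, a potassium channel, from 5.71 ± 2.71 to 116 ± 18.4 (log2FC 4.18). The largest falls were in Htr2a, a serotonin receptor, from 82.7 ± 7.72 to 2.09 ± 2.93 (log2FC -5.19), and Peg12, from 3404 ± 59.3 to 163 ± 29.0 (log2FC -4.38). Next were H19, from 5763 ± 1457 to 476 ± 168 (log2FC -3.62) and Dlk1, from 441244 ± 35918 to 47408 ± 5927 (log2FC -3.22, adjusted p = 5.46e-08). Next was Slc38a4, from 15103 ± 744 to 2329 ± 149 (log2FC -2.70). Mest rose from 1110.5 ± 409 to 4889.6 ± 321 (log2FC 2.19), Igf2 from 45183 ± 6361 to 81744 ± 17986 (log2FC 0.84) and Igf2r from 63914 ± 1878 to 94529 ± 11316 (log2FC 0.56). Grb10 fell from 458 ± 128 to 212 ± 31.2 (log2FC -1.09). Peg3 (log2FC 0.58, adjusted p = 0.133) and Plagl1 (log2FC 0.35, adjusted p = 0.283) were not called. Settings that changed a call or a sign were Igf2r (0.44 without differentiation 2), Peg3 (0.58 without quiescence 1, 0.58 without quiescence 2) and Plagl1 (0.81 without differentiation 1, -0.12 without differentiation 2, -0.20 with quantile normalization).

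Set against the quiescent preadipocyte, the day 6 culture had higher fat cell and mitochondrial transcripts and lower matrix, actin and mitotic transcripts. This comparison asked for the net change of differentiation. Of 14647 genes tested, 9717 changed, 4892 higher and 4825 lower at differentiation, and 2564 and 2555 of these by at least 2-fold. With the same total per library the median of all genes shifted by -0.227 and 37.5% of the called genes were higher (3795 higher and 6314 lower), and with quantile normalization it shifted by -0.102 and 44% were higher. The largest rises were in Retn, from 35.8 ± 17.6 to 108811 ± 90.3 (log2FC 11.62, adjusted p = 6.37e-09) and O3far1, a receptor of omega-3 fatty acids, from 3.24 ± 2.03 to 10916 ± 3980.4 (log2FC 11.37). Next was Thrsp, a regulator of lipid synthesis, from 39.7 ± 5.65 to 103434 ± 22896 (log2FC 11.30). Also among the 5 largest were Ghrh, growth hormone releasing hormone, and Pygl, liver glycogen phosphorylase, which were listed at 0 at quiescence and at 6496 ± 3467 and 3151 ± 553 at differentiation. The largest falls were in Tnmd, tenomodulin, from 763 ± 84.3 to 5.18 ± 4.26 (log2FC -7.14), and Rxfp1, a relaxin receptor, from 324 ± 151 to 3.53 ± 0.616 (log2FC -6.09). Next were Fat2, an atypical cadherin, from 1461 ± 567 to 22.5 ± 1.69 (log2FC -5.91), and Rgs8, a regulator of G protein signalling, from 1796 ± 31.3 to 30.7 ± 5.51 (log2FC -5.84). Next was Fgd3, an exchange factor, from 819.9 ± 85.7 to 13.9 ± 1.71 (log2FC -5.79).

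Of adipocyte genes, 48 of 49 rose and 0 fell, 48 and 0 adjusted over the list alone (adjusted p = 8.36e-23, or adjusted p = 0.474 with an estimated correlation). Cidec, a lipid droplet protein, rose from 307 ± 64.5 to 513328 ± 52624 (log2FC 10.71, adjusted p = 2.65e-09), Adipoq from 827 ± 118 to 509058 ± 33016 (log2FC 9.27) and Fabp4 from 2048 ± 441 to 1120470 ± 35782 (log2FC 9.11). Cebpa rose from 4222 ± 501 to 78388 ± 2782 (log2FC 4.22) and Pparg from 6169.9 ± 404 to 68445 ± 4025 (log2FC 3.47). Cebpb rose from 4764 ± 1009 to 11775 ± 416 (log2FC 1.32), while Cebpd was not called (log2FC 0.15, adjusted p = 0.368). Of early adipogenic regulators, 13 of 24 rose and 3 fell, 13 and 3 adjusted over the list alone (adjusted p = 0.0127, or adjusted p = 0.474 with an estimated correlation). Of inhibitors of adipogenesis, 5 of 28 rose and 20 fell, 5 and 20 adjusted over the list alone (adjusted p = 0.00164, or adjusted p = 0.474 with an estimated correlation). Of oxidative phosphorylation genes, 64 of 65 rose and 0 fell, 64 and 0 adjusted over the list alone (adjusted p = 5.27e-18, or adjusted p = 0.478 with an estimated correlation). Of citric acid cycle and fatty acid oxidation genes, 39 of 40 rose and 1 fell, 39 and 1 adjusted over the list alone (adjusted p = 8.55e-16, or adjusted p = 0.474 with an estimated correlation). The fall was in Cpt1a, the liver form of a carnitine transferase, from 14743 ± 1355 to 6176 ± 693 (log2FC -1.26). Of cholesterol genes, 19 of 21 rose and 0 fell, 19 and 0 adjusted over the list alone (adjusted p = 7.44e-09, or adjusted p = 0.474 with an estimated correlation). Of brown fat markers, 10 of 13 rose and 2 fell, 10 and 3 adjusted over the list alone (adjusted p = 0.0189, or adjusted p = 0.474 with an estimated correlation). Of glucocorticoid genes, 19 of 26 rose and 2 fell, 19 and 2 adjusted over the list alone (adjusted p = 2.67e-05, or adjusted p = 0.474 with an estimated correlation). The sign turned in Cebpd (-0.08 with the same total per library).

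Of the G1/S list, 7 of 46 rose and 31 fell, 7 and 33 adjusted over the list alone (adjusted p = 0.000409, or adjusted p = 0.726 with an estimated correlation). Ccnd1 fell from 62367 ± 6516 to 8832 ± 2431 (log2FC -2.84) while Brca1 and Ccne1, cyclin E1, rose (2.74 and 1.49). Of the G2/M list, 0 of 59 rose and 56 fell, 1 and 56 adjusted over the list alone (adjusted p = 9.08e-10, or adjusted p = 0.569 with an estimated correlation). Kif23, a motor of cytokinesis, fell from 3511 ± 721 to 504 ± 16.7 (log2FC -2.78, adjusted p = 7.92e-07) and Mki67 from 14332 ± 289.8 to 5580.4 ± 823 (log2FC -1.37), and Cdk1 (log2FC -0.51, adjusted p = 0.0347) and Ccnb1 (log2FC -0.57, adjusted p = 0.0437) fell less. Of CDK inhibitors and growth arrest genes, 13 of 32 rose and 9 fell, 14 and 9 adjusted over the list alone, with no call (adjusted p = 0.672) and with more falls than rises under the same total (10 and 13) and quantile normalization (11 and 13). Cdkn2c rose from 2858 ± 98.1 to 22079 ± 3547 (log2FC 2.94) and Cdkn1a from 27515 ± 3386 to 40693 ± 729 (log2FC 0.57), while Cdkn1b fell from 12895 ± 1130.1 to 6841 ± 31.9 (log2FC -0.91). Of interferon genes, 3 of 35 rose and 21 fell, 3 and 21 adjusted over the list alone (adjusted p = 0.000736, or adjusted p = 0.598 with an estimated correlation). Of inflammatory genes, 5 of 24 rose and 17 fell, 5 and 18 adjusted over the list alone (adjusted p = 0.00678, or adjusted p = 0.504 with an estimated correlation). Ccl2, a chemokine, fell from 7347 ± 254 to 272 ± 13.8 (log2FC -4.75). Of actin genes, 1 of 30 rose and 26 fell, 1 and 26 adjusted over the list alone (adjusted p = 8.31e-10, or adjusted p = 0.474 with an estimated correlation). Acta2 fell from 104777 ± 8178 to 2027 ± 549 (log2FC -5.72). Calls lost when a library was left out were Ccnb1 (-0.35 without quiescence 1, -0.65 without differentiation 1, -0.49 without differentiation 2) and Cdk1 (-0.31 without quiescence 1, -0.62 without differentiation 1, -0.39 without differentiation 2).

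Of matrix genes, 26 of 114 rose and 78 fell, 26 and 78 adjusted over the list alone (adjusted p = 1.19e-06, or adjusted p = 0.474 with an estimated correlation). Collagens had no call (adjusted p = 0.293), as 8 of 23 rose and 14 fell, 8 and 14 adjusted over the list alone. Of other matrix proteins, 10 of 54 rose and 38 fell, 10 and 38 adjusted over the list alone (adjusted p = 1.06e-05, or adjusted p = 0.474 with an estimated correlation). Of remodelling genes, 8 of 37 rose and 26 fell, 8 and 26 adjusted over the list alone (adjusted p = 7.86e-05, or adjusted p = 0.474 with an estimated correlation). Mmp9, a gelatinase, fell from 7582 ± 254 to 250.4 ± 81.5 (log2FC -4.95, adjusted p = 4.88e-08), Fmod, fibromodulin, from 6289 ± 850.4 to 302 ± 126 (log2FC -4.43) and Col12a1 from 146736 ± 43756 to 7976 ± 1397 (log2FC -4.18). Lox fell from 245868 ± 45484 to 51551 ± 6865 (log2FC -2.25) and Col1a1 from 1349400 ± 67589 to 358594 ± 47009.5 (log2FC -1.92). Fn1 fell from 487856 ± 25294 to 217817 ± 35589.9 (log2FC -1.17) and Col3a1 from 1937660 ± 53904 to 899081 ± 115670 (log2FC -1.11). Of the 61 imprinted genes, 20 rose and 28 fell, 20 and 28 adjusted over the list alone, with no call for the list (adjusted p = 0.449), nor for the paternal genes, where 8 of 27 rose and 13 fell, 8 and 13 adjusted over the list alone (adjusted p = 0.332), or the maternal genes, where 12 of 34 rose and 15 fell, 12 and 15 adjusted over the list alone (adjusted p = 0.795). Dlk1 fell from 506354 ± 81596 to 47408 ± 5927 (log2FC -3.41, adjusted p = 4.88e-08), Htr2a from 36.8 ± 19.4 to 2.09 ± 2.93 (log2FC -3.94) and Peg12 from 1133 ± 38.1 to 163 ± 29.0 (log2FC -2.80). H19 fell from 3025 ± 546 to 476 ± 168 (log2FC -2.70) and Slc38a4 from 12405 ± 1285 to 2329 ± 149 (log2FC -2.41). Grb10 fell from 507 ± 16.9 to 212 ± 31.2 (log2FC -1.26) and Igf2r from 153613 ± 24822 to 94529 ± 11316 (log2FC -0.70). Plagl1 fell from 687 ± 17.4 to 416 ± 184 (log2FC -0.80). Kcnq1 rose from 17.3 ± 8.48 to 116 ± 18.4 (log2FC 2.75), Dhcr7 from 3392 ± 366 to 21586 ± 323 (log2FC 2.67) and Igf2as from 197 ± 48.3 to 903 ± 121.6 (log2FC 2.21). Asb4, a substrate adaptor of ubiquitin ligases, rose from 16.7 ± 1.39 to 73.3 ± 3.99 (log2FC 2.07) and Ascl2, a helix-loop-helix factor, from 7.18 ± 2.40 to 33.1 ± 8.39 (log2FC 2.07). Mest rose from 3131 ± 299 to 4889.6 ± 321 (log2FC 0.64). Igf2 (log2FC 0.38, adjusted p = 0.0851), Cdkn1c (log2FC 0.76, adjusted p = 0.192) and Peg3 (log2FC -0.77, adjusted p = 0.0603) were not called. Settings that changed a call were Plagl1 (-0.82 without quiescence 1, -0.77 without quiescence 2, -0.33 without differentiation 1), Mest (0.55 to 0.74 without quiescence 1, quiescence 2, differentiation 1 or differentiation 2, 0.41 with the same total per library), Igf2 (0.57 without quiescence 2, 0.61 without differentiation 1), Cdkn1c (0.60 with a pseudocount of 10) and Peg3 (-1.43 without quiescence 1, -0.77 with a replicate block, -0.99 with quantile normalization, -1.01 with the same total per library).

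A further comparison set the quiescent libraries against the mean of proliferation and clonal expansion in a single contrast. A gene can meet it by differing from only 1 of these 2 stages, as where 29 interferon genes were higher here but 8 rose from proliferation to quiescence. Of 14647 genes tested, 8326 differed, 4164 higher and 4162 lower at quiescence, against 4899 higher and 3404 lower with the same total per library. Of the 61 imprinted genes, 26 were higher and 10 lower, 26 and 10 adjusted over the list alone, higher relative to the other genes (adjusted p = 0.0232, or adjusted p = 0.474 with an estimated correlation). The paternal genes, of which 13 of 27 were higher and 4 lower, 15 and 5 adjusted over the list alone (adjusted p = 0.0608), and the maternal genes, of which 13 of 34 were higher and 6 lower, 13 and 6 adjusted over the list alone (adjusted p = 0.0982), had no call alone. Matrix genes were mostly higher, as 62 of 114 were higher and 19 lower, 64 and 20 adjusted over the list alone (adjusted p = 0.000162, or adjusted p = 0.504 with an estimated correlation). So were CDK inhibitors and growth arrest genes, as 19 of 32 were higher and 7 lower, 19 and 7 adjusted over the list alone (adjusted p = 0.0127, or adjusted p = 0.474 with an estimated correlation), and interferon genes, as 29 of 35 were higher and 0 lower, 30 and 0 adjusted over the list alone (adjusted p = 1.38e-08, or adjusted p = 0.474 with an estimated correlation). The G1/S list, of which 0 of 46 were higher and 46 lower, 0 and 46 adjusted over the list alone (adjusted p = 1.66e-19, or adjusted p = 0.474 with an estimated correlation), and the ribosome biogenesis list, of which 0 of 49 were higher and 47 lower, 0 and 47 adjusted over the list alone (adjusted p = 6.75e-19, or adjusted p = 0.474 with an estimated correlation), were lower. So was the cholesterol list, of which 0 of 21 were higher and 19 lower, 0 and 20 adjusted over the list alone (adjusted p = 1.38e-08, or adjusted p = 0.474 with an estimated correlation).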

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

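The tests added later, defined above, were chosen after the data were seen. Without 1 library, its stage keeps a lone library, which is assumed to vary like the others. The planned edgeR and DESeq2 fits were not run.

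The counts of changed genes stayed within 1.5 times of those reported with pseudocounts of 0.5 and 10, a mean of at least 50, the 3 other scalings, no variance trend, a replicate block and both tests added later. From proliferation to quiescence, 3472 genes were reported, and 1757 were called with no filter, 1942 with only the stages compared, where fewer libraries inform the spread, and 1304 to 3536 without 1 library. For imprinted genes it was 24, against 14 with no filter and 14 to 26 without 1 library. The cause was not tested for the drops with no filter and without proliferation 2. Tested by treat against a 2-fold change, a stricter question, 149 genes (5 imprinted) changed from proliferation to quiescence, 2664 (11) from quiescence to clonal expansion, 3942 (23) from there to differentiation, 3178 (16) from quiescence to differentiation, and 702 differed in the contrast of quiescence with the mean of 2 stages. Without 1 library, the counts of the last 4 comparisons stayed within 1.5 times of those reported. With a replicate block, the 5 comparisons gave 4005, 10378, 10931, 10068 and 8713 genes. With the length and GC trend removed they gave 4609, 10217, 10738, 10086 and 8806. Of camera's 70 list calls, 0 remained with an estimated correlation, and fry made 111. The estimated correlation was 0.8372 in the G2/M list and 0.7932 in the G1/S list, far above the preset 0.01. It was -0.0042 in the imprinted list, which lost its calls too, so correlation is not the whole cause. With an estimated correlation, camera also rests on the 4 residual degrees of freedom alone, a further reason for fewer calls. From proliferation to quiescence, the imprinted list had an unadjusted camera p of 0.0139 at the preset correlation and 0.0359 with the estimated one. Fry asks whether the members changed at all, and camera whether they changed relative to the other genes.

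Of the 232 named changes, 211 were called. Over 12 alternatives, 2682 of 2784 values kept their direction and side of the threshold, 66 lost a call, 20 gained it and 16 changed sign. With the same total, signs changed in Fabp4 (-0.10) and Fn1 (-0.20) from quiescence to clonal expansion and Cebpd (-0.08) from quiescence to differentiation. That scaling moved the median of all genes to -0.239 and -0.227, so these changes follow from it. With quantile normalization, signs changed in Fn1 (-0.31) and Grb10 (0.32) from quiescence to clonal expansion and Plagl1 (-0.20) from there to differentiation. The cause there was not tested. Without 1 library, log2FC ranged from -0.03 to 0.15 in Cdkn1b, -0.25 to 0.03 in Cebpd and -0.26 to 1.05 in Peg3 from proliferation to quiescence, from -0.08 to 0.36 in Fabp4, -0.02 to 0.08 in Fn1, -0.46 to 0.11 in Grb10 and -0.22 to 0.03 in Mki67 from quiescence to clonal expansion, and from -0.22 to 0.04 in Col3a1 and -0.12 to 0.81 in Plagl1 from there to differentiation. Depth was not varied, and the genes near the limit of a mean of 10 rest on the fewest reads.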

Other observations

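The tests of marker lists, and of random lists of genes in the deposited values, were set before their results were seen, and the other tests below after.

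Genes that mark other cell types also changed. The counts here follow the order of the 4 stage comparisons above, and adjusted over the list alone they were the same unless given. Of 7 macrophage and blood markers, 1, 2, 1 and 1 rose and 1, 1, 5 and 5 fell, with no call (adjusted p at least 0.11). Of 7 endothelial markers, 1, 2, 3 and 0 rose and 1, 3, 3 and 6 fell (4 in the second comparison adjusted over the list alone), with no call (adjusted p at least 0.0877). Of 14 muscle, bone and cartilage markers, 3, 1, 7 and 5 rose and 4, 9, 4 and 7 fell (6 in the first adjusted over the list alone), and the list was called in the second (adjusted p = 0.0452, or adjusted p = 0.474 with an estimated correlation). Against that fall, Alpl, the alkaline phosphatase of bone, rose at clonal expansion from 85.5 ± 17.8 to 5931 ± 823 (log2FC 6.11, adjusted p = 1.34e-07). Des, the muscle filament desmin, rose at differentiation from 183 ± 66.2 to 5282 ± 409 (log2FC 4.89, adjusted p = 8.46e-08). Of 6 epithelial markers, 1, 1, 5 and 5 rose and 2, 1, 0 and 1 fell, with a call in the third comparison (adjusted p = 0.0435, or adjusted p = 0.474 with an estimated correlation) and none in the fourth (adjusted p = 0.0632). Krt18, a keratin of simple epithelia, rose at differentiation from 0.486 ± 0.656 to 1256 ± 644 (log2FC 9.70, adjusted p = 3.02e-07).

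Experiments 1 and 2 differed in the same genes at quiescence and at clonal expansion (r = 0.537 across 11949 genes with a mean of at least 100 and a known length). The libraries share a stage, so no biological explanation was tested. Removing a trend on length and GC content left r = 0.454, which argues against these as the whole cause, although the longest transcript is an imperfect length. A trend with length between the quiescent libraries may be part of it, with rho 0.646 at quiescence and -0.007 at proliferation. The nuclear RNA Malat1, chosen after its values were seen, was at 49650.5 and 287450 in the quiescent libraries but also at 87798.5 and 219275 at proliferation and 58276.5 and 175438 at clonal expansion, while Neat1, chosen likewise, was at 89298.3 and 85511.8 at quiescence, and handling of the RNA stays open.

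At quiescence, 26 imprinted genes were higher and 10 lower than the mean of proliferation and clonal expansion, an excess of 16. Of 10000 random lists matched on mean value, 0.64% had as large an excess (95% between -9 and 12), which argues against a chance pick, though genes of a list may move together. The excess was 17 with quantile normalization, which argues against the scaling (21 with the same total per library, where genes in general moved up), and 15 without quiescence experiment 2, which argues against its length trend. In the 56 genes with a known length it was 12 as deposited and 11 with the trend on length and GC content removed. Of random lists 4.53% reached 11, within their 95% range (-10 to 12), so chance stays open there. A tie of imprinted genes to the resting stage is a hypothesis, and a change from only 1 of the 2 stages or regulation shared with matrix genes stays open.

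Adipoq and other fat cell genes rose at quiescence before any cocktail. If a small share of cells were like those of day 6, the rise of Adipoq would put it at 0.1558%. Of 11 other markers with a low baseline, 3 (Retn, Thrsp and Slc2a4) imply less than it divided by 3, where the median was 0.1314%. Other cells were assumed constant. The bound of more than 1 in 4 was set after seeing the values and fails with 1 marker fewer, so this cannot decide. Such cells and cells at an earlier step of adipogenesis stay open.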
